A study of Mus musculus with 9 samples.

How the data were processed

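Tumour tissue of male mice aged 4 to 6 months, with Cre recombinase under the probasin promoter and floxed Pten and Smad4, was profiled on 9 Affymetrix arrays with biotin labelling of 6 ug of total RNA. The samples were 2 treatment-naive DLP, 3 CRPC DLP, and 1 each of AP, DLP, VP and a lung metastasis from 1 CRPC reporter mouse. The deposited values are log2 probe set signals, which the authors made with the Transcriptome Analysis Console and normalized between arrays; its version and its summarisation method are not given in the sources used here. The values have 2 decimals and cover 45037 probe sets. The sorted values of the arrays differed by a median of 0.05 log2 within the 5 DLP arrays and within the 4 reporter mouse arrays, but by 0.31 over all 9. From this the 2 sets were treated as normalized separately, which the labels do not state. Comparisons were therefore made within a set, and no value of one set was subtracted from a value of the other. Each array has 1 value per probe set and no count of reads, so the number of arrays sets the precision.

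Probe sets were assigned to genes with the annotation of the array. Of the 45037, 34945 had 1 gene symbol, 932 had several and 9160 had none in the annotation used here, Pten, Ar, Nkx3-1 and Spp1 among the last. Symbols were checked against a reference table through the Entrez ID, which changed 0 of them, left 34741 unchanged and did not find 204. No coordinates are given, since a probe set measures a transcript and not a position. All probe sets entered the tests with no filter on level. For gene lists and named genes, each of 18193 genes was represented by its probe set with the highest mean over the 9 arrays. A probe set whose name marks it as binding several transcripts may measure a mixture.

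CRPC and treatment-naive DLP were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all probe sets, threshold 0.05), with 2 against 3 arrays and no covariate. The SE of a difference is the moderated one. For the 35 gene lists, limma's camera was run with its preset correlation of 0.01 between genes and Benjamini-Hochberg over the lists, and then with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks only whether the genes of a list move. Lists needed at least 5 measured members. Within each list, p-values were also adjusted over the list alone, which was not in the plan and does not correct for the number of lists. The p-values adjusted in this way came from a second limma fit, to 1 probe set per gene, whose moderated SE differs slightly from the one printed. With the p-values of the fit to all probe sets the same 18 list members were past 0.05. The test was tested on simulated data of the same size with 200 changed among 45037 probe sets. In 20 simulations limma recovered 30% of those changed 1.5-fold, 54% at 2-fold and 84.8% at 4-fold, with 3.8 false calls on average. Each simulated probe set took the spread observed in these arrays as its true spread. Some probe sets had identical values within each group, where any change is easily found, so the recovered shares may be too high. A list shifted by 0.4 log2 was called in 20 of 20 simulations, and 0.15 unshifted lists were called on average. The simulated genes were independent, while the estimated correlation in the real lists reached 0.86 (cell cycle). The simulated rates for lists therefore need not hold for the real data.

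The metastasis and the lobes have no replicates, so no test was run. Probe sets were counted whose value lay at least 1 log2 (2-fold) above or below all 3 lobes, or, for a lobe, both other lobes. List medians were placed among 10000 random lists of the same size drawn from 20 bins of mean level. Python 3.11.15 with NumPy 2.4.6 and Matplotlib 3.10.9 prepared the annotation and the figures.

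The tests, except the adjustment over a list alone, the gene lists and the rule for named genes were chosen before the data were examined. The lists cover prostate secretory proteins, androgen response, luminal, luminal progenitor and basal epithelium, squamous keratinization, neuroendocrine genes, cell cycle, epithelial-mesenchymal transition, fibroblasts and matrix, smooth muscle, endothelium, T, NK and B cells, macrophages, granulocytes, myeloid-recruiting chemokines, dendritic cells and MHC class II, MHC class I, interferon, hypoxia and glycolysis, oxidative phosphorylation, cholesterol and steroid synthesis, glucocorticoid response, WNT and YAP targets, early response, lung epithelium, lung endothelium and alveolar macrophages, seminal vesicle, erythroid cells, adipocytes, skeletal muscle, and nerve. Named genes in the DLP comparison were the 12 highest and 12 lowest log2 differences past the threshold with groups apart, and places left over went to the smallest unadjusted p in each direction. As no probe set passed, all 24 were filled in that way. For the metastasis 10 genes per direction were named by their difference from the nearest lobe, and for each lobe 5 per direction. Up to 4 members of each list with the smallest p or the largest difference were named, and a fixed set of genes of prostate biology, 15 of them measured here, was named whatever the values. Predicted genes, RIKEN clones and receptor or immunoglobulin variable genes were kept out of the named genes, except as list members. Vip, Cd163 and Cxcl1, and the genes of single arrays and the further fibroblast genes in the closing observations, fall outside this rule and were chosen after their values were seen.

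Alternatives covered the normalization (quantile, median centring), a filter on dim probe sets (mean over the 9 arrays above the 30th percentile), the variance moderation, array weights, a fit over all 9 arrays, the threshold, the replicate number as a block, each array or lobe left out in turn, other size thresholds and other reference lobes. The planned addition of the reporter mouse DLP as a further CRPC sample, and the planned reading of the DLP calls in the reporter mouse, were left out because the sets of arrays were treated as normalized separately.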

Results

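Transcript levels were measured on 9 Affymetrix mouse expression arrays, each holding 45037 probe sets, in prostate tumours of mice that lose Pten and Smad4 in the prostate epithelium through a probasin-driven Cre recombinase. Castration-resistant prostate cancer (CRPC) here is tumour that grew after surgical castration followed by a diet with enzalutamide, an androgen receptor antagonist. The first set held 5 arrays of the dorsolateral prostate (DLP), 2 from treatment-naive tumours and 3 from CRPC tumours. The labels do not say that each replicate is a separate animal, and every SD, SE and p below treats them as independent. A second set came from 1 CRPC mouse with the mTmG fluorescent reporter, and held 1 array each of the anterior prostate (AP), the DLP, the ventral prostate (VP) and a lung metastasis. The labels mention no sorting of cells. Values are log2 probe set signals, and array medians were 5.99 to 6.00 in the first set and 6.28 to 6.29 in the second. The number of arrays limits the precision of every value, and the reporter mouse gave no replicates. Each gene is represented by 1 probe set, and probe sets of Pten, Ar, Nkx3-1 and Spp1 had no symbol in the annotation used here.

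The comparison of CRPC with treatment-naive DLP asks which transcripts differ between tumours that grew after castration and enzalutamide and untreated ones. Most genes of granulocytes and of the chemokines that recruit myeloid cells had higher values in CRPC DLP. Both lists were past the threshold with a preset correlation between genes but not with an estimated one (adjusted p = 0.263 with an estimated correlation for each). Their estimated correlations, -0.021 and -0.0036, were not above the preset 0.01, so a higher correlation does not explain this loss. With an estimated correlation, camera refers its statistic to the 3 residual degrees of freedom of these arrays, which it does not do with a preset one. The loss thus reflects the small number of arrays, and the unadjusted p by camera was then 0.00814 and 0.0225. Cxcl2, a ligand of the granulocyte receptor Cxcr2, was 9.46 ± 0.17 (SD, n = 2) in naive and 10.87 ± 0.19 (SD, n = 3) in CRPC DLP, a 2.66-fold difference. The S100a8 and S100a9 values, which encode the subunits of calprotectin, were higher by 0.99 ± 0.20 and 1.01 ± 0.26 log2 (SE). In the other direction, most genes of fibroblasts and extracellular matrix had lower values, a list likewise not past the threshold with an estimated correlation (adjusted p = 0.662 with an estimated correlation). Its member Col6a1, a collagen VI chain, was 10.22 ± 0.16 (SD, n = 2) in naive and 9.21 ± 0.12 (SD, n = 3) in CRPC DLP. No single probe set passed the limma test over all probe sets, so every difference of a single gene below is given as a value with its SE.

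Of the 21 measured granulocyte and granulocytic myeloid-derived suppressor cell genes, 19 had a higher mean in CRPC and 2 a lower one, and the median log2 difference was 0.44. By limma, 0 of them were past 0.05 when adjusted over all probe sets. Adjusted over the list alone, uncorrected for the number of lists, 9 were past 0.05, all higher. Among these were Trem1 (0.44 ± 0.036, adjusted p = 0.00478 over the list), a receptor that amplifies inflammatory signalling in neutrophils, Clec4e (0.90 ± 0.17), Il1b (0.61 ± 0.097) and Cxcr2 itself (0.55 ± 0.11), these last 3 with adjusted p = 0.0274 over the list. The S100a8 probe set is of a type that can also bind related transcripts. The competitive test of the list against all other genes gave an adjusted p = 1.72e-07 with a preset correlation between genes, and adjusted p = 0.263 with an estimated correlation. Chemokines and cytokines that recruit myeloid cells had a median of 0.36, with 19 of 23 higher (adjusted p = 0.000488, and adjusted p = 0.263 with an estimated correlation). Past 0.05 when adjusted over the list alone were Cxcl2 (1.41 ± 0.14), Cxcl5 (0.83 ± 0.13) and Il1b, while Ccl20 (1.53 ± 0.39), which attracts cells bearing Ccr6, was not. Another Cxcr2 ligand on the list, Cxcl1, was measured by 3 probe sets. The 1 that stood for it in the list, of a type that can bind related transcripts, differed by 0.23 ± 0.076, and the other 2 by 0.62 ± 0.058 and 0.60 ± 0.060. Without naive replicate 2 the chemokine list was no longer past the threshold (adjusted p = 0.189). Natural killer and cytotoxic cell genes had a median of 0.16, 12 of 13 higher, with examples Tbx21 (0.24 ± 0.063) and Klrd1 (0.38 ± 0.15). Their adjusted p = 0.00759, adjusted p = 0.662 with an estimated correlation, and adjusted p = 0.0643 without naive replicate 1.

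Androgen response genes were lower in CRPC DLP in 18 of 25 cases, with a median of -0.12 (adjusted p = 0.000287, and adjusted p = 0.263 with an estimated correlation). Mme, which encodes the peptidase neprilysin, was 7.92 ± 0.078 (SD, n = 2) in naive and 6.11 ± 0.35 (SD, n = 3) in CRPC DLP, a difference of -1.81 ± 0.22 (SE). Mme and the fatty acid elongase Elovl7 (-0.52 ± 0.090) were past 0.05 when adjusted over the list alone by limma (adjusted p = 0.0231 and 0.0452). Fkbp5, a chaperone gene induced by androgen and glucocorticoid receptors, differed by -0.84 ± 0.22 and the transcription factor gene Zbtb16 by -0.71 ± 0.20, neither past it. Of the Fkbp5 probe sets that did not stand for it in the list, 1 differed by -0.565 ± 0.061 (unadjusted p = 0.000573 by limma). Another differed by -0.058 ± 0.061, and neither was adjusted over the list. Glucocorticoid response genes, which share Fkbp5 and Zbtb16, had a median of -0.25 and did not pass (adjusted p = 0.0938). Among 10 measured prostate secretory protein genes 5 were higher and 5 lower, so the median was 0.0083 while the mean was -0.42 (adjusted p = 0.478). Of these, 9530002B09Rik was 8.07 ± 0.45 (SD, n = 2) in naive and 4.71 ± 0.20 (SD, n = 3) in CRPC DLP, and Wfdc15b was higher in CRPC by 1.02 ± 0.16. Both were past 0.05 by limma when adjusted over the list alone (adjusted p = 0.000906 and 0.0119), and neither when adjusted over all probe sets. Apof differed by -2.05 ± 0.60, and Pbsn, the androgen-regulated gene whose promoter drives the Cre recombinase, had signals near the lowest of the arrays in both groups, 3.21 ± 0.34 (SD, n = 2) and 3.57 ± 0.32 (SD, n = 3).

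Stromal and vascular lists were among the lower ones. Of 21 fibroblast and matrix genes 20 were lower, with a median of -0.50 (adjusted p = 2.28e-08, and adjusted p = 0.662 with an estimated correlation). Against the other 4 arrays, the matrix genes had a median of 0.62 in naive replicate 1, 0.17 in naive replicate 2, -0.32 and -0.46 in CRPC replicates 1 and 2, and 0.10 in CRPC replicate 3. Col6a1 was the only member past 0.05 when adjusted over the list alone (adjusted p = 0.0111), and Col6a3 (-0.88 ± 0.24) and the receptor gene Pdgfrb (-0.40 ± 0.082) were not. A second Pdgfrb probe set differed by -0.043 ± 0.13. Endothelial genes were lower in 16 of 18 cases with a median of -0.29, among them Sox17 (-0.61 ± 0.14) and Tie1 (-0.39 ± 0.090), with adjusted p = 1.27e-05 and adjusted p = 0.662 with an estimated correlation. In CRPC replicate 3 their median against the other 4 arrays (0.079) was above that in naive replicate 2 (0.058). Smooth muscle genes had a median of -0.23 (11 of 15 lower), including Myh11, a smooth muscle myosin (-0.40 ± 0.075), of which a second probe set went the other way (0.12 ± 0.073). Their adjusted p = 0.0261, and adjusted p = 0.799 with an estimated correlation, was lost without naive replicate 2 (adjusted p = 0.611) and without CRPC replicate 2 (adjusted p = 0.167), and naive replicate 2 also carried skeletal muscle transcripts (Acta1 at 10.77). Epithelial-mesenchymal transition genes had a median of -0.25, 13 of 19 lower (adjusted p = 0.0225, and adjusted p = 0.803 with an estimated correlation), and were past the threshold in 2 of the 5 fits that left out 1 array (lost without naive replicate 1, CRPC replicate 1 or CRPC replicate 2, with adjusted p = 0.868, 0.109 and 0.146). Their members went both ways, as Sparc differed by -0.56 ± 0.29, Mmp9 by 0.60 ± 0.19 and Vim by -0.28 ± 0.30.

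Basal epithelial, cell cycle and interferon lists were also lower. Basal epithelial genes had a median of -0.23, 15 of 18 lower (adjusted p = 0.00106, adjusted p = 0.662 with an estimated correlation, and adjusted p = 0.0628 without naive replicate 2), with Itga6 at -0.18 ± 0.069 and Krt5 at -0.29 ± 0.24. Cell cycle genes had a median of -0.39, 26 of 29 lower (adjusted p = 5.87e-05, adjusted p = 0.803 with an estimated correlation, and adjusted p = 0.0591 without CRPC replicate 2). Single CRPC samples differed, since the proliferation marker Mki67 was 8.59, 8.40 and 9.40 in them against 9.28 ± 0.057 (SD, n = 2) in naive DLP. Interferon response genes had a median of -0.20, 22 of 25 lower (adjusted p = 0.00386, and adjusted p = 0.803 with an estimated correlation), but the mean difference turned from -0.18 to 0.091 without naive replicate 2, and the call was also lost without CRPC replicate 2 or 3 (adjusted p = 0.163 and 0.0812) and with the replicate number as a block (adjusted p = 0.171). Among luminal keratin and adhesion genes, Krt8 was at 0.12 ± 0.097, Epcam at -0.067 ± 0.087 and Cdh1 at -0.23 ± 0.099. The luminal list had a median of 0.030 (adjusted p = 0.99, test direction lower). Luminal progenitor genes (median -0.081, adjusted p = 0.674) held the aldehyde dehydrogenase gene Aldh1a1 at -1.54 ± 0.42, and squamous keratinization genes had a median of -0.19 (adjusted p = 0.324). Neuroendocrine genes had a median of 0.038 and a mean of -0.15 (adjusted p = 0.99), with Syp at 0.14 ± 0.071 and Chga at 0.037 ± 0.15. Smad4, deleted in the epithelium of all these mice, was 9.67 ± 0.035 (SD, n = 2) in naive and 9.35 ± 0.16 (SD, n = 3) in CRPC DLP, and no wild-type sample gives its reference level.

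The other lists did not pass the threshold, and the means of several turned direction with 1 naive array left out. Among these were hypoxia genes (0.19, but -0.11 without naive replicate 1), T cell genes (0.11, but -0.10 without naive replicate 2) and skeletal muscle genes (-0.73, but 0.049 without naive replicate 2). Among immune lists, macrophage genes had a median of 0.11 (adjusted p = 0.211), dendritic cell and MHC class II genes 0.19 (adjusted p = 0.295), T cell genes 0.11 (adjusted p = 0.443), B and plasma cell genes 0.12 (adjusted p = 0.324) and MHC class I genes -0.016 (adjusted p = 0.973). For metabolism and signalling, the medians were 0.19 for hypoxia and glycolysis (adjusted p = 0.116), 0.036 for oxidative phosphorylation (adjusted p = 0.324), -0.09 for cholesterol and steroid synthesis (adjusted p = 0.213), -0.09 for YAP targets (adjusted p = 0.15), -0.03 for WNT targets (adjusted p = 0.434) and 0.068 for early response and stress genes (adjusted p = 0.637). Markers of tissues that a dissection can include had medians of -0.44 for skeletal muscle (adjusted p = 0.125), 0.043 for nerve and Schwann cells (mean -0.14, adjusted p = 0.894), 0.13 for adipocytes (adjusted p = 0.15), 0.13 for erythroid cells (adjusted p = 0.443) and -0.13 for seminal vesicle (adjusted p = 0.154). Single arrays of both groups stood apart in such genes. The muscle actin gene Acta1 was 10.77 in naive replicate 2 and at most 5.34 in the other 4 DLP arrays, and Adipoq was 4.4 in CRPC replicate 1 and at most 3.2 in the others. The neuropeptide gene Vip, on no list, was 8.47 in naive replicate 1 and at most 3.73 in the others, while the nerve list median of that array was 0.038 above them. Without that array the mean difference of the nerve list turned from -0.14 to 0.18. Lung epithelial genes had a median of 0.01 (mean -0.0090, adjusted p = 0.99) and lung endothelial and alveolar macrophage genes 0.05 (adjusted p = 0.988, test direction lower), with Foxf1 (0.42 ± 0.056) past 0.05 when adjusted over the latter list alone (adjusted p = 0.0195). A second Foxf1 probe set went the other way (-0.15 ± 0.089).

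Ranked by the 1 probe set that represents each gene, the genes with the smallest unadjusted p in each direction were separated between the groups in every sample. Each had an adjusted p = 0.692 by limma. Other probe sets of a gene were not ranked, and a second one of Bcl2l14 differed by 1.035 ± 0.045 (unadjusted p = 1.22e-05). On the higher side, besides Trem1 and Cxcl2, stood Fpr2 (0.69 ± 0.064), a formyl peptide receptor of phagocytes, Bcl2l14 (0.91 ± 0.089), a member of the Bcl2 family, Pde9a (0.93 ± 0.098), a cyclic GMP phosphodiesterase, and Tifa (0.40 ± 0.042), an adaptor in NF-kappaB signalling. A2ml1, Pla2g4f, Ttc32, Socs5, Asgr1 and Tacc2 were higher by 0.33 to 0.58. On the lower side, besides Col6a1, stood Dnase1l2 (-1.67 ± 0.18), a deoxyribonuclease, Ttc9 (-1.37 ± 0.11), Pdlim2 (-0.99 ± 0.061), Dmrt2 (-0.98 ± 0.10) and Ror2 (-0.56 ± 0.037), a receptor for Wnt5a. Isoc2b, Miga1, Bmyc, Sptssa, Arhgap42 and Moxd1 differed by -0.71 to -0.43, while a second Arhgap42 probe set differed by -0.023 ± 0.039.

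**Figure D1:**
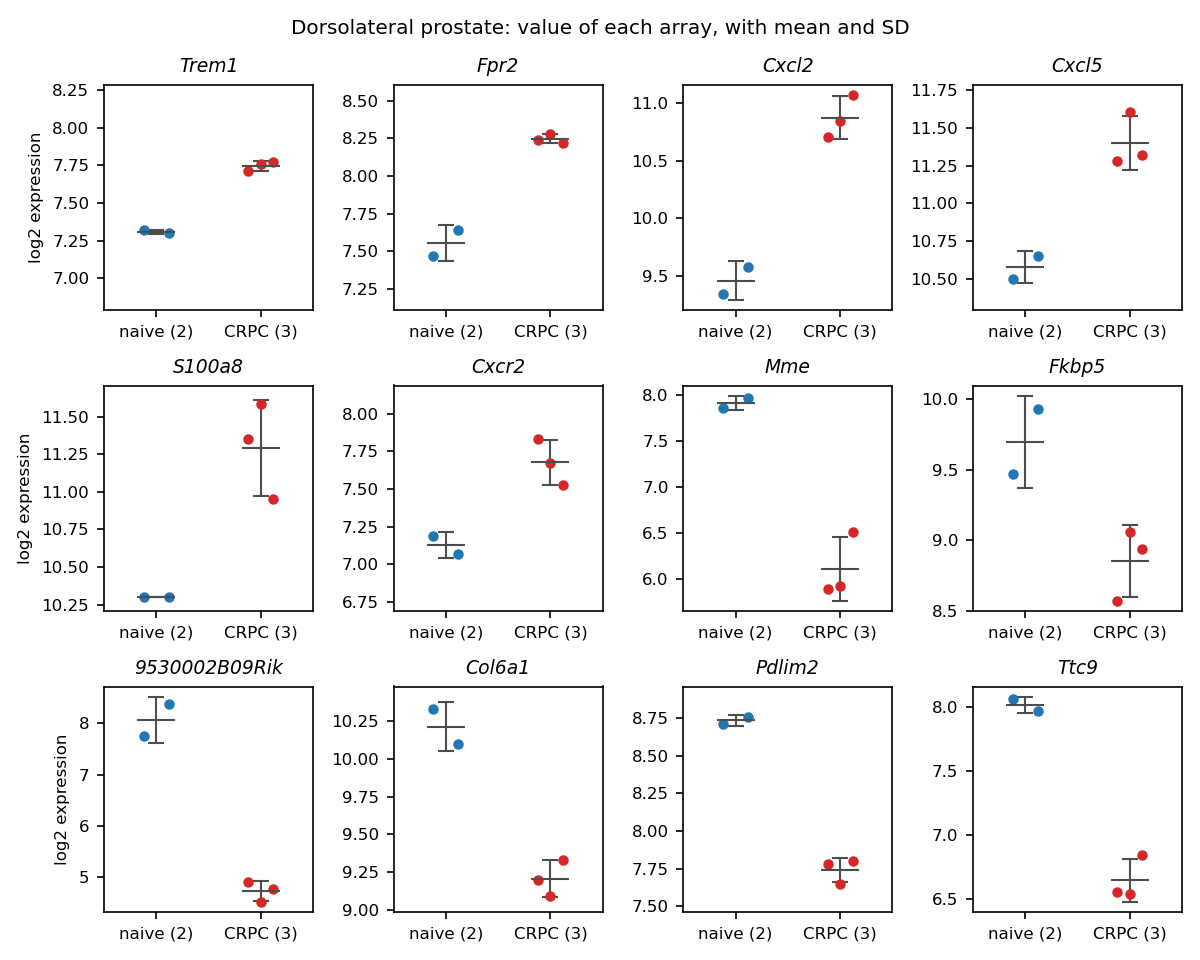
Log2 probe set signal (vertical axis, a separate range for each gene) of 12 genes in the 5 DLP arrays, with each point 1 array, the long bar the mean of a group (2 treatment-naive in blue, 3 CRPC in red) and the whiskers 1 SD. Cxcl2 sits between 9.34 and 9.58 in the naive and between 10.7 and 11.07 in the CRPC samples.

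**Figure D2:**
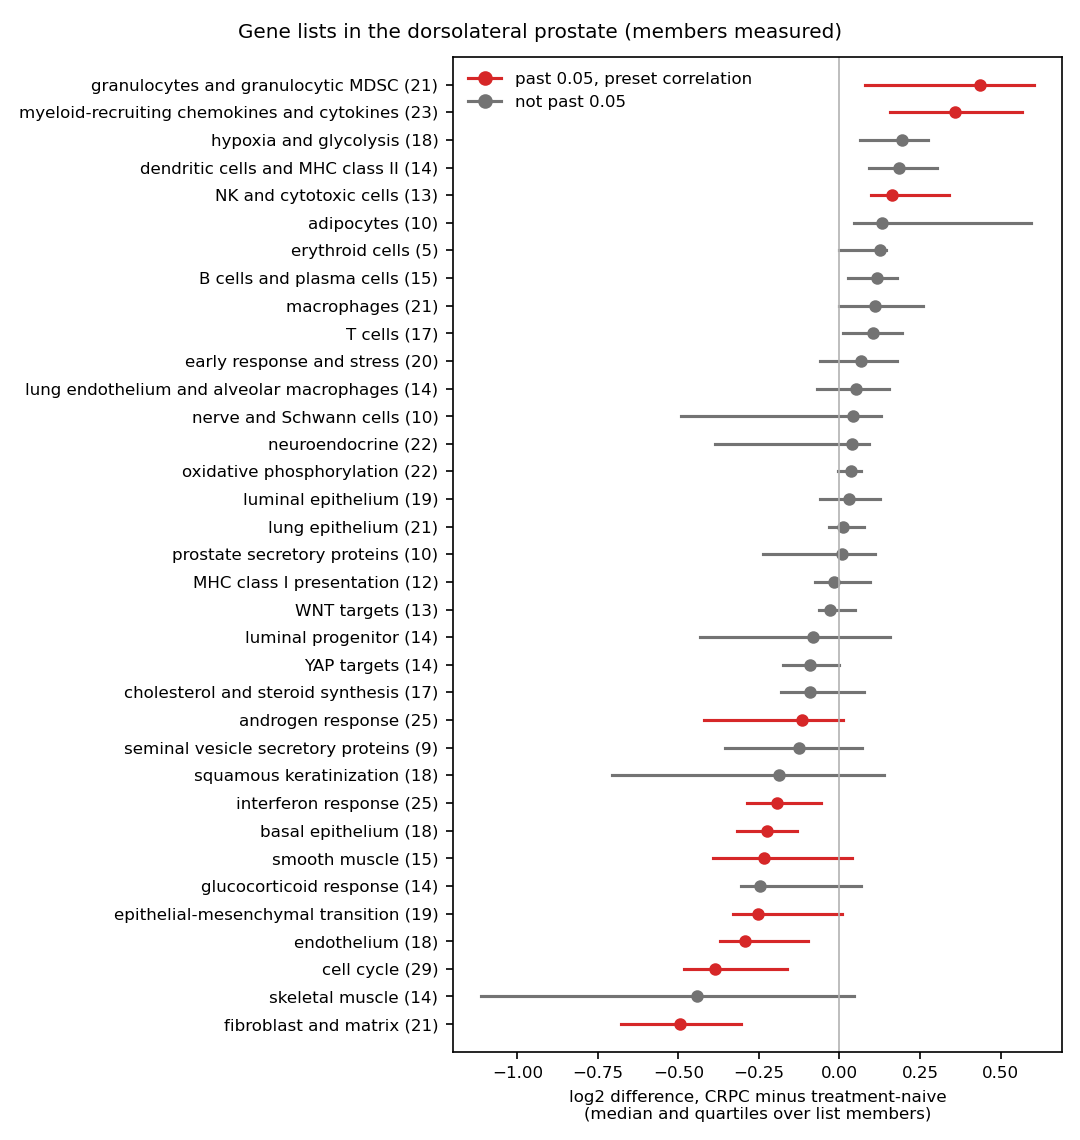
Log2 difference, CRPC minus treatment-naive DLP, of each gene list, with the point at the median over the members, the line from the lower to the upper quartile and the number of measured members in parentheses. Red marks the 11 lists past an adjusted p of 0.05 with the preset correlation, of which 0 are past it with an estimated one, and the medians run from -0.50 for fibroblast and matrix genes to 0.44 for granulocyte genes.

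In the limma test of 2 against 3 arrays, 0 of 45037 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.549. At an unadjusted p under 0.05 there were 2786 (1656 higher, 1130 lower), or 6.19% against a nominal 5%, and 66 of them differed at least 2-fold. Other splits of the same arrays into 2 and 3, made after the results were seen, gave up to 2621. The groups did not overlap at 7303 probe sets, or 16.2%, where chance gives 20% if no values are tied. Pairs of DLP arrays had identical values at 13.2% to 16.8% of probe sets, so the chance share lies under 20% and was not computed. Of 35 lists, 11 passed with the preset correlation (3 higher, 8 lower) and 0 with an estimated one or with limma's rotation test (fry) for genes moving one way. The variant of that test for genes changing in either direction was past 0.05 for 4 lists, those of granulocytes, chemokines, prostate secretory proteins, and lung endothelium with alveolar macrophages. The estimated correlation was 0.51 for fibroblast and matrix, 0.45 for endothelial and 0.86 for cell cycle genes. It was -0.0093 for androgen response genes, under the preset value. Camera with an estimated correlation also rests on only 3 residual degrees of freedom, so few lists could pass with it. The p-values rest on the spread between these 5 arrays, and the median SD within a group was 0.090 log2.

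The lung metastasis was set beside the 3 primary lobes of the same mouse to ask which transcripts differ between a metastasis and its primary tumour. It carried the transcripts of lung at high levels. Scgb1a1, the club cell secretory protein, was 13.63 in the metastasis and at most 4.21 in the lobes, a difference of at least 685-fold. Surfactant genes of alveolar type 2 cells were also far above the lobes, with Sftpc at 14.18 (at least 474-fold above each lobe) and Sftpa1 at 13.15 (422-fold). Of the 21 fibroblast and matrix genes on the list, 16 lay below every lobe and 4 above every lobe. Among all genes, the values far below the lobes included Cilp at 5.13 (at least 15.7-fold below each lobe), Thbs2 at 4.92 (12.1-fold) and Lum, a collagen-binding proteoglycan on the list, at 6.69 (6.59-fold).

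In all, 869 probe sets lay at least 2-fold outside all 3 lobes, 675 higher and 194 lower in the metastasis. As yardsticks, the same count against the other 3 samples of the mouse was 72 for AP, 26 for DLP and 24 for VP, and each CRPC DLP replicate lay 2-fold outside the other 2 at 56, 107 and 125 probe sets. Also far above every lobe were Scgb3a2 (at least 124.5-fold), Hc, the complement component C5 (at least 83.3-fold), Chil3, a product of alveolar macrophages (82.7-fold), Ager, a marker of alveolar type 1 cells (57.3-fold), the fibrinogen gene Fgg (48.5-fold), Inmt (46.2-fold) and Itih4 (43.1-fold). Far below every lobe were Gpc6 (9.13-fold), Col12a1 (8.88-fold), Serpinf1 (8.28-fold), Pi16 (7.94-fold), Sfrp4 (7.84-fold), Car3 (6.92-fold) and Meg3 (5.94-fold). The folds are against the nearest lobe and describe 1 sample of 1 mouse, with no test. Lobe signals of Scgb1a1, Sftpc, Sftpa1, Scgb3a2, Hc, Chil3, Ager, Fgg and Itih4, and metastasis signals of Cilp, Thbs2, Gpc6, Pi16, Sfrp4 and Car3, lay under the array medians. Where such a signal is at background its fold is a lower bound. The values do not show which are, so the order of these folds is not interpreted.

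Gene lists are given as the median log2 difference between the metastasis and the mean of the 3 lobes, with its percentile among 10000 random lists of the same size and expression level. Lung epithelial genes had a median of 1.95, and 15 of 21 were at least 2-fold above every lobe, while 9 of the 21 were above the array median in all 3 lobes. Lung endothelial and alveolar macrophage genes had a median of 0.90 with 6 of 14 at least 2-fold above. General endothelial genes had a median of 1.66, all 18 above every lobe, including Sox17 (2.48), Ptprb (2.31) and Cldn5 (2.30), the last a tight junction gene. B and plasma cell genes had a median of 1.22, with Ms4a1, which encodes CD20, 2.82 above the lobe mean. Granulocyte genes had a median of 1.13 against the mean of the lobes and 0.52 against the DLP alone, with Clec4d (2.38), Mmp8 (1.78), S100a9 (1.30), S100a8 (1.27) and Cxcr2 (1.27). Chemokine genes had a median of 0.40, which was 0.14 against the DLP alone, with Cxcl3 at 1.97, Cxcl5 at 0.82 and Ccl8 at -1.64. Glucocorticoid response genes (0.41), early response genes (0.32) and squamous genes (0.23, but -0.033 without AP) also had medians above the lobes. These 9 medians were each at the 100th percentile. Macrophage genes had a median of 0.16 (99.9th percentile) and went both ways, with the lysozyme gene Lyz2 at 2.03, Gpnmb at 2.87 and Cd163 at -1.23.

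Fibroblast and matrix genes had the lowest median, -1.36, with 10 of 21 at least 2-fold below every lobe and 2 at least 2-fold above. Interferon response genes had a median of -0.68, which was -1.20 against AP, -0.81 against VP and -0.09 against DLP, and included the chemokine Cxcl9 at -2.06. Hypoxia and glycolysis genes had a median of -0.47, among them the carbonic anhydrase Car9 at -1.66. Adipocyte genes had a median of -0.39, with Adipoq at -3.08, although Cd36, a fatty acid receptor also made by endothelium, was at 4.63. Cell cycle genes had a median of -0.31, which was 0.16 against AP alone, and Mki67 was at -0.21. Smooth muscle genes had a median of -0.22, with 5 of 15 at least 2-fold below, including Tagln (-1.91) and Acta2 (-1.74). The medians of MHC class I (-0.28), cholesterol and steroid synthesis (-0.20, but 0.09 against AP alone), epithelial-mesenchymal transition (-0.21), basal (-0.15, but 0.24 against AP alone), oxidative phosphorylation (-0.11) and neuroendocrine genes (-0.16) were also in the lowest 2.5% of the random lists. Within these, the epithelial-mesenchymal transition median turned to 0.10 when dim probe sets were left out, Vim was at 0.82, Krt5 at -0.12, Chga at -0.19 and Syp at -0.22, while Foxa2, a factor of lung and neuroendocrine cells, was at 1.63.

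The medians of the luminal, luminal progenitor, androgen response and prostate secretory lists lay near the lobes. Luminal genes had a median of -0.037 (50th percentile), but 0.12 against VP alone, with Krt8 at -0.027, Cdh1 at 0.083 and Epcam at -0.28, while the mucin Muc1 was at 2.48 and the prostate homeobox gene Hoxb13 at -1.61. Androgen response genes had a median of -0.093 (8.2 percentile), with Fkbp5 at -0.093 and Mme at 1.82. Prostate secretory genes had a median of -0.19 (2.67 percentile), with Apof at -2.13 and Pbsn at -0.08, and seminal vesicle genes one of -0.053 (70.6 percentile). Only 2 of 10 secretory and 0 of 9 seminal vesicle genes were above the array median in all 3 lobes, so these medians rest mostly on dim signals. Luminal progenitor genes had a median of 0.078 (97 percentile), but -0.17 against the DLP alone, with Aldh1a1 at 3.37, and Smad4 was at 0.26. The remaining medians were 0.12 for natural killer cells, 0.098 for YAP targets, 0.097 for dendritic cells and MHC class II, 0.027 for T cells (-0.0050 without VP), 0.033 for erythroid cells, -0.037 for WNT targets, -0.10 for skeletal muscle and -0.12 for nerve. Of the 35 lists, 25 had a median in the lowest or highest 2.5% of the random lists. Random lists hold unrelated genes, so a list whose genes move together reaches these tails more easily. T cell genes, at 0.027, were among the 25 (97.65 percentile). Single lobes reached the tails too, as cell cycle genes did in AP (-0.79) and VP (0.51) against the other lobes.

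**Figure D3:**
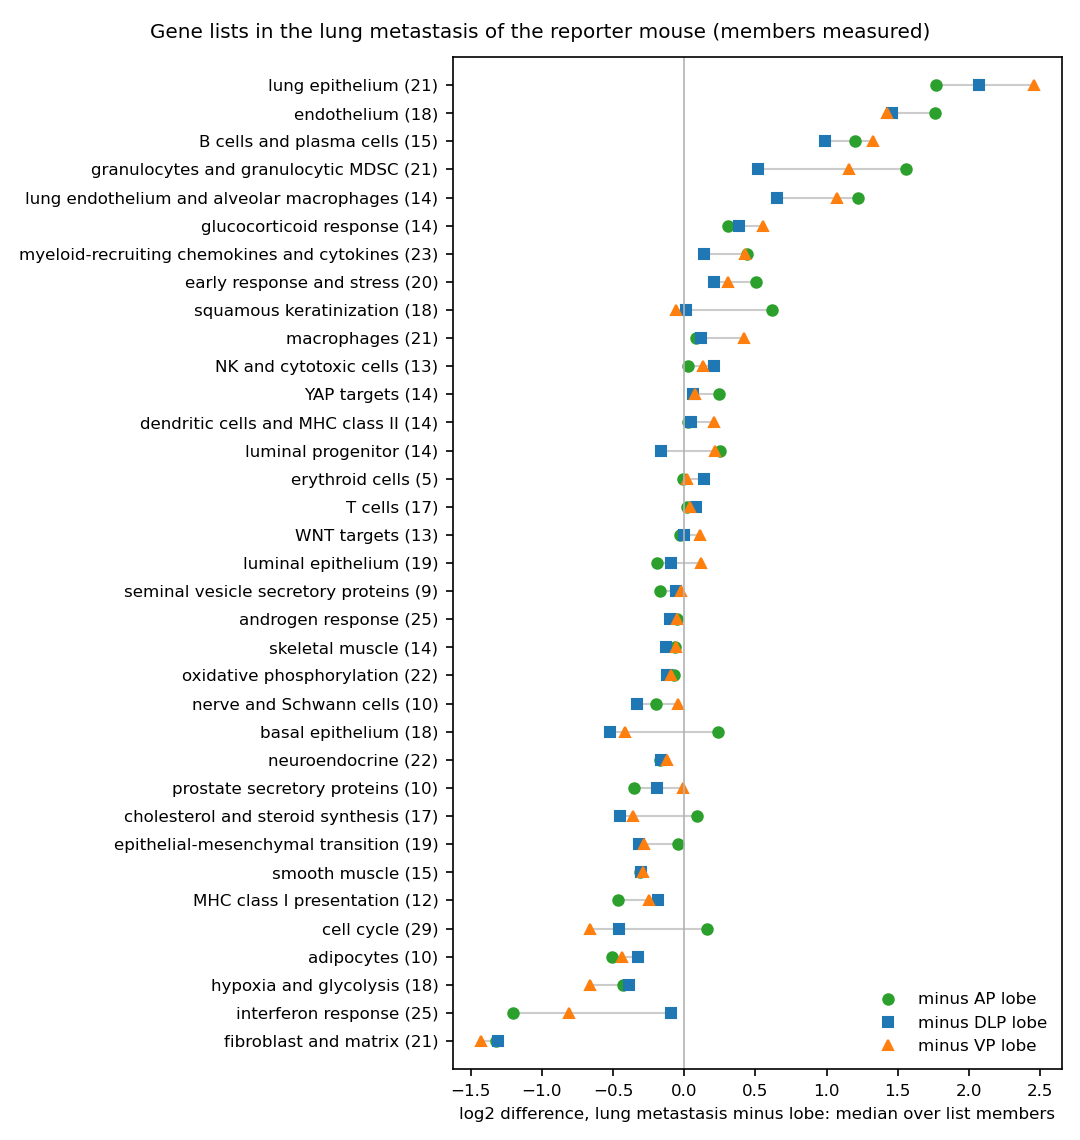
Log2 difference between the lung metastasis and each primary lobe of the reporter mouse, as the median over the members of each gene list, with a circle for AP, a square for DLP and a triangle for VP, 1 sample each. Lung epithelial genes lie between 1.77 and 2.46 above the lobes, and fibroblast and matrix genes between -1.43 and -1.31.

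The 3 lobes of the reporter mouse were compared with each other to describe how CRPC differs between lobes. Spink1, a trypsin inhibitor, was 10.92 in AP, 5.29 in DLP and 5.17 in VP. Reg3b, an antimicrobial lectin, was 11.11 in AP, 9.09 in DLP and 6.03 in VP, and Lypd8 was 11.48, 9.43 and 5.44. In DLP, Klk1b16, a kallikrein, was 6.60 against 3.86 in AP and 3.89 in VP, and the adipocyte hormone Adipoq was 4.68 against 7.88 and 7.83. In VP, the cornified envelope gene Sprr1b was 6.21 against 3.72 in AP and 4.19 in DLP.

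At least 2-fold outside both other lobes were 135 probe sets in AP (58 higher, 77 lower), 64 in DLP (49 higher, 15 lower) and 64 in VP (11 higher, 53 lower). Wif1 and Tff3 were also higher in AP, and the water channel Aqp4, Mmp13, Serpinb2, Krt6a and S100g were lower there. Uox, Muc4 and Saa1 were higher in DLP, as was the skeletal muscle gene Acta1 (7.2 against 4.93 in AP), and Car3, Cyp2e1, Ifi27l2a and Ddx60 were lower. Rec8, Gpihbp1, Rgs4 and Adamts18 were higher in VP, and Reg1, Upk1b and Apod were lower there with Lypd8 and Reg3b. Against the mean of the other lobes, interferon response genes had a median of 0.61 in AP and -0.90 in DLP, cell cycle genes -0.79 in AP and 0.51 in VP, squamous genes -0.63 in AP, and granulocyte genes 0.72 in DLP. With 1 sample per lobe none of these was tested.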

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

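These alternatives were chosen before the data were examined, except the granulocyte list without genes that other lists hold, which was chosen after seeing the data. In the DLP comparison 0 probe sets passed by limma under 2 normalizations, 3 other variance models, the filter on dim probe sets, the replicate block, an adjusted p of 0.10 and each array left out. A fit over all 9 arrays repeats the same test by construction, since groups of 1 array add no estimate of the spread. The 2 criteria that gave a count were an unadjusted p under 0.05 with at least 2-fold (66) and limma without moderation (8). These 8 differed by 0.04 to 0.09 log2 and had identical values within each group, in values given to 2 decimals. Pairs of DLP arrays had identical values at 13.2% to 16.8% of probe sets, and pairs of reporter mouse arrays at 2.04% to 3.45%. Both sets have 2 decimals, so rounding alone does not account for the higher share, whose cause was not tested. With 1 array left out, the count at an unadjusted p under 0.05 ranged from 2376 (without CRPC replicate 1) to 5910 (without naive replicate 1), with 4833 without naive replicate 2. It was 1910 without moderation and 2040 with dim probe sets left out. With 1 naive sample left, that sample is assumed to vary like the CRPC samples. The 24 genes named by p were chosen by p from these same arrays, and all had their groups apart. Their direction under alternatives therefore says nothing about stability, and 0 of their 334 values passed an adjusted p of 0.05 (smallest 0.189). Replicate numbers are shared by 2 pairs of samples only, and nothing in the labels pairs them otherwise. The replicate block gave 0 calls, 2705 probe sets at an unadjusted p under 0.05 and 13 lists, which held 10 of the 11 and not the interferon response (adjusted p = 0.171).

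Of 35 lists, 11 passed with a preset correlation, 0 with an estimated correlation and 0 with fry, 14 after quantile normalization, 11 after median centring and 11 without dim probe sets. Leaving out 1 array gave 9 (without CRPC replicate 2) to 17 lists (without naive replicate 1). The lists of granulocytes, androgen response, endothelium, and fibroblasts and matrix were past the threshold in 5 of 5 such fits. Without the 4 members that other lists hold, the granulocyte list of 17 genes had a median of 0.44 (adjusted p = 2.38e-06), where the adjusted p of the whole list ranged from 8.65e-07 to 0.000663 with 1 array left out and was 0.263 with an estimated correlation. Other values near 0 turned direction, and the cause was not tested. After quantile normalization the mean of MHC class I genes was 0.0019. With dim probe sets left out, lung endothelial and alveolar macrophage genes were at -0.017, nerve genes at 0.20, WNT targets at 0.061, and epithelial-mesenchymal transition genes in the metastasis at 0.10. In the replicate block, lung epithelial genes were at 0.030 and MHC class I genes at 0.018.

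With 1 array left out in turn, Chga differed by -0.08 to 0.16, Epcam by -0.14 to 0.0033 and Vim by -0.60 to 0.047. Over the same fits the list means ranged from -0.17 to 0.35 for B and plasma cells, -0.13 to 0.015 for cholesterol and steroid synthesis, -0.13 to 0.43 for dendritic cells and MHC class II, -0.11 to 0.49 for hypoxia, -0.45 to 0.091 for interferon response, -0.082 to 0.15 for luminal epithelium, -0.029 to 0.059 for lung endothelium and alveolar macrophages, -0.033 to 0.030 for lung epithelium, -0.018 to 0.31 for macrophages and -0.13 to 0.096 for MHC class I. They ranged from -0.46 to 0.18 for nerve, -0.41 to 0.11 for neuroendocrine genes, -1.50 to 0.049 for skeletal muscle, -0.89 to 0.057 for squamous genes, -0.10 to 0.33 for T cells and -0.051 to 0.010 for WNT targets. In the metastasis, with 1 lobe left out, squamous genes ranged from -0.033 to 0.24 and T cells from -0.0050 to 0.055.

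The count of probe sets outside all 3 lobes moved with the size threshold by its construction, to 1868 at 1.5-fold (1384 higher, 484 lower) and 213 at 4-fold (186 higher, 27 lower). The lower count was 357 against the mean of the lobes and 419 against the DLP alone. For the lobes the total was 1201 at 1.5-fold (AP 660, DLP 268, VP 273) and 34 at 4-fold (AP 14, DLP 8, VP 12). The addition of the reporter mouse DLP to the CRPC group and the reading of the DLP calls in the reporter mouse were not run, because the sets of arrays were treated as normalized separately. For single genes of the DLP comparison, 539 values under alternatives kept direction and side of the threshold and 4 turned direction, a count that includes the 24 genes chosen by p. For its lists 303 did so, 34 lost the threshold, 21 gained it and 26 turned. In the metastasis, 216 list values stayed within their spread, 24 moved and 3 turned, and 104 gene values stayed and 36 moved. Signals near the lowest values of the arrays, such as Pbsn, say little about low expression.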

Other observations

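All tests described here were chosen after the results were seen. Some genes departed in single DLP arrays. In treatment-naive replicate 1 these included the neuropeptide gene Vip at 8.47 (at most 3.73 in the others), Uchl1 at 8.03 (at most 5.77) and Nefl at 6.16 (at most 3.99). The median of the nerve list there was 0.038 above the other arrays, but the mean CRPC minus naive difference of that list turned from -0.14 to 0.18 without this array. Naive replicate 2 held skeletal muscle genes (list median 1.04 above the other arrays), with Acta1 at 10.77 (at most 5.34), Tnnc2 at 9.19 (at most 4.92) and Neb at 5.87 (at most 2.68). In CRPC replicate 1 they included Rec8, at 8.13 (at most 6.04). In CRPC replicate 2 they included Calm4 at 8.93 (at most 5.81) and Crisp3 at 5.74 (at most 2.89). CRPC replicate 3 had the highest Il6, 7.07 (at most 5.13), and the lowest Olfm4, a gene of progenitor-like epithelium, at 9.2 (at least 11.85 in the others). At least 2-fold outside all 4 other arrays were 92 probe sets in naive replicate 1, 83 in naive replicate 2, and 23, 46 and 64 in CRPC replicates 1 to 3.

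Fibroblast genes split in the lung metastasis. Of 21, 16 lay below the mean of the lobes and 5 above it. The collagen gene Col1a1 was 8.5 in the metastasis and at least 10.66 in the lobes, and Fbln2 was 6.6 against at least 9.15. Above the lobe mean were the small proteoglycan gene Ogn (by 2.81), the growth factor receptor gene Pdgfra (by 1.69), Dpt (by 0.87), Gsn (by 0.65) and Pdgfrb (by 0.62). Across 18193 genes, the difference between CRPC and naive DLP and that between the metastasis and the lobes had a Pearson r of -0.018 and a Spearman rho of -0.13, and genes are not independent replicates.

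The lung genes of the metastasis may come from normal lung tissue in the sample. Genes of lung endothelium and alveolar macrophages, which are not typical of epithelial tumour cells, had a median of 0.90 above the lobe mean, and the macrophage gene Chil3 was at 11.54. Their lower quartile of 0.10 lies slightly above 0, and 4 of these 14 genes were above the array median in all 3 lobes. As genes of other cells, they cannot show which cells made the lung epithelial transcripts, so tumour cells as a source of those stay open. Sftpc, at 14.18, had the highest signal of the array, and Scgb1a1 was at 13.63. How much of the 869 probe sets comes from lung and how much from the tumour stays open, with 1 sample and no tumour-free lung.

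The lower matrix genes of the metastasis could reflect dilution of the tumour by lung. Basal epithelial genes fell less, with a lower quartile of -0.47 against the matrix median of -1.36. Their median depended on the lobe, at 0.24 against AP and -0.52 against DLP. They cannot decide on dilution, since no tumour-free lung shows whether lung also holds these transcripts. The prostate homeobox gene Hoxb13 had a log2 difference of -1.61, close to the matrix genes. A different stroma in the lung than in the prostate, as the site of the sample gives, remains open and was not tested.

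The higher granulocyte genes of CRPC DLP might reflect other tissue, such as nerve or muscle, in the naive samples, or 1 naive array. Dilution would raise luminal genes alike, and their upper quartile was 0.13 against a granulocyte median of 0.44, while the granulocyte mean of 0.40 was 0.37 without naive replicate 2 and 0.43 without naive replicate 1. The 10 splits of the 5 arrays are too few for a share under 0.05, and the granulocyte mean was 0.40 in the real split, which 1 of 10 reached, and at most 0.31 in the others. For the number of lists past the threshold the real value was 11 and the others ran from 6 to 14, and 5 of the 10 splits gave at least 11. The treatment itself and any difference between the mice stay open and cannot be separated here.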
